A study of Mus musculus with 19 samples.

How the data were processed

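RNA was measured in 19 oral tumour samples of C57BL/6J mice after 4NQO, in 5 groups taken from the sample titles: vehicle (4), regorafenib (4), anti-PD1 (3), regorafenib with anti-PD1 (5) and anti-CD40 (3). Per the labels' protocols, RNA was isolated with a kit that also recovers DNA, and libraries were made with a stranded kit that selects polyadenylated mRNA. Per the submitters' processing notes, cutadapt 2.4, STAR 2.7.2a and the mouse build GRCm38 were used. The counting tool, its strand setting and the annotation release are not given in the sources used here. Genes that overlap, lie antisense to another gene or share reads with a near-identical copy are therefore uncertain.

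The deposited table holds whole-number counts per gene for 55487 versioned Ensembl genes in 19 columns, not normalized, and each column was matched to a sample by its name. Totals ran from 16776177 to 24969492 counts per library. Symbols and coordinates came from GENCODE release M21 on GRCm38, where 55227 IDs matched without the version, 54435 with it and 260 not at all. Of the tested genes 15 had no symbol. Coordinates are 1-based and cover the whole gene, exons, introns and untranslated regions included.

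Genes with low counts were removed with edgeR's filterByExpr by group, which left 16909 genes holding 99.92% of counts. Libraries were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with 1 mean per group over all 19 libraries (14 residual degrees of freedom, common dispersion 0.0345, median prior degrees of freedom 4.74). All groups entered 1 fit so that they share an estimate of the spread. The 7 tests were each treatment against vehicle, the combination against each single drug, and the interaction of regorafenib and anti-PD1. P-values are two-sided and were adjusted by the method of Benjamini and Hochberg over all tested genes, with a threshold of 0.05. Levels are counts-per-million (CPM) of the TMM-scaled counts, given as mean ± SD, and log2 CPM used a prior count of 2. Fold changes are the log2 estimates of the edgeR fit at its default prior count, given ± SE. The SE is the absolute log2 change divided by the square root of the F statistic. Where a group had 0 counts, a fold was set against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% interval.

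Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, except those said below to be added. The 35 lists hold 507 genes of immune, stromal, vascular, epithelial and contaminating tissues and of pathways, including 5 sex genes that were used only as a check of the labels. The other 34, each with at least 5 tested genes, were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, a self-contained rotation test. A list's mean log2 CPM in each library served as its score. The rule for named genes took the 8 largest rises and 8 largest falls among passing genes with a symbol that is not a predicted one and a mean of at least 1 CPM in some group, or, where none passed in a direction, the 3 with the smallest p. It added the 3 members with the smallest p in the direction of each list called, of which the text prints up to 3 in order of p, and 14 fixed genes against vehicle. Some genes that the rule takes are not reported here. Where a gene is named as leading a list, it has the smallest p of the members that moved in the list's direction.

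The alternatives were RLE scaling, no filter, DESeq2 1.42.0, limma with sample weights, only the groups compared, the replicate number as a block, the skeletal muscle score as a covariate, a fold threshold and leaving out each library in turn. A covariate of Y-linked genes was planned only if the libraries split into low and high; they did not, so it was not run. Added after the data were seen were the salivary gland score as a covariate, offsets for exon length and GC content (known for 16889 genes), the number of the deposited column as a block, and a list of 22 stomach genes. Comparisons that share the vehicle libraries were set beside 20 simulations of unchanged groups and beside splits of the vehicle libraries 2 and 2. The genes called with regorafenib were followed in the other treatments in the same 2 ways, which was added after the data were seen, with the regorafenib calls given their measured fold in the 20 simulations and all other groups drawn at the vehicle means. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 12.9). Components were computed from the 500 most variable genes on log2 CPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

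The 6 comparisons of 2 groups were tested on simulated data with 200 changed genes each. Of genes changed 1.5-fold, 52.2% were recovered for regorafenib against vehicle (16737 genes), 48.5% for anti-PD1 (16790), 53% for the combination (16749) and 47.7% for anti-CD40 (16746). For the combination against regorafenib (16733 genes) and against anti-PD1 (16723 genes) the shares were 53.8% and 43.9%. At 2-fold they ranged over the 6 comparisons from 70.1% for anti-PD1 to 80.6% for the combination against regorafenib, and at 4-fold from 87.9% to 95.5% for the same comparisons. False calls made up 2.01% (combination against anti-PD1) to 6.54% (anti-PD1) of calls. The interaction was not simulated.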

Results

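Gene expression was measured by RNA sequencing in oral squamous cell carcinomas of C57BL/6J mice. The tumours were induced with 4-nitroquinoline 1-oxide (4NQO), a carcinogen that damages DNA, supplied at 100 µg/ml for 10 weeks from an age of 6 weeks. The 19 samples comprised 4 from mice on vehicle, 4 on regorafenib, 3 on an antibody against PD1, 5 on regorafenib with anti-PD1 (the combination), and 3 on an agonist antibody against CD40. Regorafenib is an oral inhibitor of several kinases, among them receptors for vascular endothelial and platelet-derived growth factors. The labels give 5 mg/kg/day for regorafenib and state no separate dose for the combination. PD1 is an inhibitory receptor of T cells encoded by Pdcd1, and CD40 is a receptor that activates antigen-presenting cells. Library totals ranged from 16776177 counts in combination 2 to 24969492 in vehicle 1, and levels below are in counts-per-million (CPM). The labels do not state that each sample came from a separate animal, so p-values measure the spread between these samples, which may be technical in part.

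Salivary gland transcripts set the widest spread between libraries. The first principal component held 55% of the variance of the 500 most variable genes, the second 16.1% and the third 7.54%. Treatment group accounted for 13.2% of the spread along the first, 41.8% along the second and 52.1% along the third. Leading genes of the first component included Bpifb2, a secreted salivary protein, and Muc5b, a gland mucin, which were named after the component was seen. The mean log2 CPM of the 11 tested salivary gland genes ran from -1.54 in vehicle 3 to 6.62 in vehicle 2. Each treatment's mean of this score differed from vehicle by less than the spread between libraries (two-sided exact permutation tests, smallest unadjusted p = 0.349 over 4 comparisons, with the combination, adjusted p = 0.83 in each). The mean of 19 skeletal muscle genes was lower with regorafenib than with vehicle, by a log2 difference of -0.40 (exact permutation p = 0.0571, adjusted p = 0.228 over 4 comparisons, smallest possible p 0.0286). Differences from vehicle were 0.07 with anti-PD1, 0.09 with the combination and 0.12 with anti-CD40 (exact permutation, adjusted p = 0.714 in each).

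**Figure D1:**
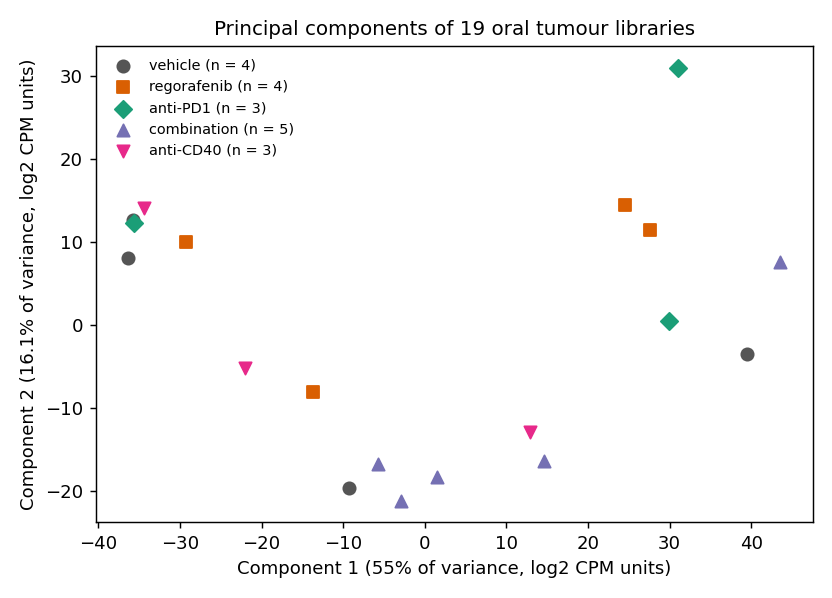
Principal components of the 19 libraries from the 500 most variable genes, with component 1 (55% of variance) on the horizontal axis and component 2 (16.1%) on the vertical axis, both in log2 CPM units. Each point is a library and each colour and shape a treatment group, and libraries of every group lie on both sides of 0 on the first component.

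Regorafenib alone was compared with vehicle to find what the kinase inhibitor changed in the tumours. Genes of basal and wound-type keratinocytes, cell division, glucose use and T cells were higher as lists with regorafenib, and genes of skeletal muscle, pericytes and M2-type macrophages were lower. Each of these list calls was lost with an estimated correlation (adjusted p = 0.32 with an estimated correlation in each). Krt14 (ENSMUSG00000045545.8, chromosome 11 from 100203162 to 100207548), the keratin of basal epithelial cells, stood at 4070 CPM ± 522 (SD, n = 4) against 2130 ± 469 (n = 4), a log2 change of 0.93 ± 0.20 (SE; edgeR adjusted p = 0.0134). Slc2a1 (ENSMUSG00000028645.11, chromosome 4 from 119108711 to 119137983), a glucose transporter, rose from 78.1 CPM ± 8.55 to 150 ± 25.3, a log2 change of 0.94 ± 0.13 (adjusted p = 0.00136). Ryr1 (ENSMUSG00000030592.18, chromosome 7 from 29003344 to 29125179), the calcium release channel of skeletal muscle, fell from 1030 CPM ± 77.2 to 635 ± 38, a log2 change of -0.69 ± 0.11 (adjusted p = 0.00267). Of 16909 genes tested, 562 rose and 507 fell, 54 and 26 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 4147 genes, against 845 expected by chance, and the median absolute log2 change of the genes called was 0.42. Genes that rose had a median exon length of 3340 bases and genes that fell 6786, against 3942 for all tested genes, while with length and GC offsets the medians were 4693 and 4629. The number of calls was 464 without vehicle 3, 269 without vehicle 4, 473 without regorafenib 1, 645 without regorafenib 3 and 280 without regorafenib 4. With the skeletal muscle mean as a covariate it was 86. There the median log2 change of the 1069 genes, in the direction of the fit without the covariate, was 0.32 in place of 0.42. The median SE was 0.10 in both fits.

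The largest rises belonged to genes of the stomach. Pgc (ENSMUSG00000023987.14, chromosome 17 from 47726842 to 47734482), which encodes a pepsinogen, stood at 34.2 CPM ± 20 with regorafenib and 0.0553 ± 0.0489 with vehicle (adjusted p = 0.00656). Its level was 41.2, 38.2, 5.46 and 51.9 CPM in regorafenib 1 to 4, and 2.35 CPM in anti-CD40 1. Pla2g1b (ENSMUSG00000029522.12, chromosome 5 from 115466262 to 115474722), a secreted phospholipase, was at least 136-fold higher and Atp4b, a subunit of the gastric proton pump, at least 35.9-fold higher, against floors of 3 counts over the vehicle group. The count ratio to vehicle was 929 (95% interval 166 to 36700) for Gkn1 and 372 (103 to 3080) for Gkn2, both gastrokines. It was 127 (34.8 to 1060) for Mucl3 and 103 (28.1 to 856) for Atp4a, the catalytic subunit of the gastric proton pump. These intervals and floors cover counting error only. Clps, which encodes colipase, stood at 9.95 CPM ± 5.66 against 0.0454 ± 0.0331. Of a list of 22 stomach genes, written after these genes were seen, the 18 that were higher in these libraries took 0.0112%, 0.00729%, 0.00128% and 0.015% of the counts in regorafenib 1 to 4. They took 0.00177% in anti-CD40 1 and at most 0.000339% in each of the other libraries.

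The 8 largest falls with regorafenib lay between -1.53 and -1.03 on the log2 scale. Sgcd (ENSMUSG00000020354.15, chromosome 11 from 46896253 to 47988969), a sarcoglycan of the muscle membrane, fell from 8.73 CPM ± 1.49 to 4.07 ± 0.766 (log2 change -1.10 ± 0.15, adjusted p = 0.00136). Siglec1, a receptor of tissue macrophages, fell from 1.35 CPM ± 0.603 to 0.558 ± 0.133 (adjusted p = 0.0446), and Mylk3, a myosin kinase, from 1.96 ± 0.361 to 0.947 ± 0.111. The others were Cyp2b19, Doc2b, Adora1, Cdh22 and n-R5-8s1, a ribosomal RNA gene whose reads can be shared with near-identical copies. Of the 44 named genes that passed in this comparison, 16 passed whichever of its 8 libraries was left out. Between 19 and 33 passed without a regorafenib library (30, 33, 30 and 19 for regorafenib 1 to 4). Without vehicle 1 to 4, 34, 38, 25 and 19 passed. Siglec1, Adora1, Cdh22, Cd8a and Ddr2 each lost the call in 7 of the 8 runs, and Gkn2, n-R5-8s1, Hbb-bs, Lipe, Nfkbia and Pdgfrb in 6 (adjusted p up to 0.169).

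Camera called 17 of 34 gene lists between regorafenib and vehicle, 10 higher and 7 lower, with its preset correlation. With an estimated correlation the adjusted p was 0.32 for 15 of them, 0.351 for neutrophils and 0.683 for the type I interferon response. The skeletal muscle mean was lower in the same libraries, and the stomach genes were higher in them. Of 18 proliferation genes, 7 rose (16 adjusted over the list alone), with a median log2 change of 0.43 (camera adjusted p = 2.09e-12). They included Mcm5, a subunit of the replicative helicase (26.2 CPM ± 4.25 against 15.7 ± 2.7), and Aurka, a mitotic kinase (9.25 ± 0.551 against 5.77 ± 0.607). Of 13 basal keratinocyte genes, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 1.27e-05). Itga6, an integrin of the basal surface, changed by 0.58 ± 0.11. Of 11 wound and hyperproliferative keratin genes, 5 rose (5 adjusted over the list alone, median 0.51, camera adjusted p = 0.00109). Krt6b and Krt6a rose by 0.83 and 0.51, and because these paralogs are near-identical their separate counts are uncertain, while Krt16 rose by 0.89. Among 16 hypoxia and glycolysis genes, 5 rose (6 up and 1 down adjusted over the list alone, median 0.26, camera adjusted p = 0.00317), including Pfkp, a phosphofructokinase, by 0.46 ± 0.09.

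Immune and stromal lists moved in both directions with regorafenib. Of 9 genes of cytotoxic T and NK cells, 4 rose (5 adjusted over the list alone, median 0.87, camera adjusted p = 2.61e-05, adjusted p = 0.32 with an estimated correlation). Cd3e, part of the T-cell receptor complex, was at 1.34 CPM ± 0.22 against 0.498 ± 0.191, and Cd8a, a co-receptor of cytotoxic T cells, at 0.914 ± 0.314 against 0.3 ± 0.0508 (adjusted p = 0.0328). Among 13 T-cell checkpoint and regulatory genes, Tnfrsf18 passed (2 adjusted over the list alone, median 0.60, camera adjusted p = 0.00317, 0.32 with an estimated correlation). Of 15 CD40 and NF-kappa-B targets, 2 rose (4 adjusted over the list alone, median 0.19, camera adjusted p = 0.0168, 0.32 with an estimated correlation), with Nfkbia, an inhibitor of NF-kappa-B, at 0.47 ± 0.13. Dnajb1 of 14 immediate early and heat shock genes and Hbb-bs of 6 erythrocyte genes passed (1 and 4 adjusted over the list alone, medians 0.17 and 0.74, camera adjusted p = 0.0213 and 0.00109, 0.32 with an estimated correlation in both). The neutrophil list had a median of 0.66 over 13 genes with no gene passing (1 adjusted over the list alone, camera adjusted p = 0.0319, 0.351 with an estimated correlation), and its leading member Cxcr2 stood at 0.59 ± 0.18. Without vehicle 4 or regorafenib 3 the CD40 and NF-kappa-B call was lost (adjusted p up to 0.0872). The immediate early call was lost without vehicle 3, regorafenib 2 or regorafenib 3 (up to 0.124), and the neutrophil call without vehicle 1, 3 or 4 or regorafenib 3 (up to 0.102).

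Lower with regorafenib were 6 of 19 skeletal muscle genes (13 adjusted over the list alone, median -0.42, camera adjusted p = 4.16e-07, adjusted p = 0.32 with an estimated correlation). Neb, the giant thin-filament protein nebulin, fell from 1550 CPM ± 179 to 978 ± 89.3. Of 16 kinases that regorafenib targets, 2 fell, Ddr2 by -0.46 ± 0.12 and Pdgfrb by -0.51 ± 0.14 (5 down and 1 up adjusted over the list alone, median -0.16, camera adjusted p = 0.0136, 0.32 with an estimated correlation). Pdgfrb is also one of the 12 pericyte and smooth muscle genes, of which 2 fell (4 adjusted over the list alone, median -0.21, camera adjusted p = 0.0136, 0.32 with an estimated correlation), the other being Abcc9 at -0.52 ± 0.12. Of 15 M2-type macrophage genes, 1 fell (3 adjusted over the list alone, median -0.23, camera adjusted p = 0.0213, 0.32 with an estimated correlation): Cd163, a haemoglobin scavenger receptor of macrophages, went from 18.3 CPM ± 3.66 to 9.18 ± 1.71 (adjusted p = 0.00656). Lipe of 8 adipose genes fell (2 adjusted over the list alone, median -0.97, camera adjusted p = 0.0168, 0.32 with an estimated correlation). The 10 mast cell and eosinophil genes (median -0.44, camera adjusted p = 0.0168, 0.32 with an estimated correlation, leading member Gata2) and the 18 type I interferon genes (median -0.34, camera adjusted p = 0.0415, 0.683 with an estimated correlation, leading member Mx2) held no gene that passed, also when adjusted over the list alone. The adipose call was lost without vehicle 2 (adjusted p = 0.0988), the M2 call without vehicle 1 (0.0565), and the interferon call without vehicle 2, vehicle 4 or regorafenib 1 (up to 0.323). With the muscle covariate, 7 of the 17 calls were not made, among them skeletal muscle, pericytes, the kinase targets and the wound keratins.

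Anti-PD1 was compared with vehicle to find what blocking the checkpoint changed. Genes of antigen presentation and the interferon-gamma response, T cells, dendritic cells and M1-type macrophages were higher as groups, while no single gene passed the test over all genes. Camera called 19 of 34 lists, 18 higher and 1 lower. Of these, 6 held with an estimated correlation, namely antigen presentation (adjusted p = 0.0317), T-cell checkpoints (0.031), cytotoxic cells (0.0317), dendritic cells (0.0317), M1-type macrophages (0.0365) and erythrocytes (0.0375). All 19 tested antigen presentation genes passed when adjusted over the list alone, with 0 over all genes and a median log2 change of 0.76 (camera adjusted p = 4.46e-34). Its leading members were Gbp2, an interferon-induced GTPase, at 42.3 CPM ± 18.8 (n = 3) against 13.4 ± 3 (n = 4), and Cd74, the class II invariant chain, at 188 ± 38.2 against 101 ± 23.1 (adjusted p = 0.158 and 0.171). By edgeR 0 genes passed and 1576 reached an unadjusted p under 0.05, against 845 expected, while limma with sample weights called 3 and DESeq2 71. The edgeR count was 2 without vehicle 2, 1 without vehicle 3, 3 with no filter on low counts and 2 with the muscle covariate.

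The smallest adjusted p-values with anti-PD1 were those of Rac2, Ccl2 and n-R5-8s1, none of which passed. Rac2 (ENSMUSG00000033220.7, chromosome 15 from 78559167 to 78572783), a GTPase of blood cells, stood at 5.34 CPM ± 0.243 against 2.92 ± 0.381, a log2 difference of 0.87 ± 0.13 (adjusted p = 0.0594). Irf8 (ENSMUSG00000041515.10, chromosome 8 from 120736358 to 120756694), a transcription factor of myeloid and dendritic cells, stood at 7.64 ± 0.677 against 3.53 ± 1.18 (adjusted p = 0.126), and Ccl2, a monocyte chemokine, at 4.98 ± 1.23 against 1.01 ± 0.339 (adjusted p = 0.119). The lowest p-values among lower genes belonged to n-R5-8s1, Ankrd12 and Mycbp2, which did not pass (smallest adjusted p = 0.119). Of the T-cell lists, 7 of 13 checkpoint genes and 4 of 9 cytotoxic genes passed when adjusted over the list alone (0 over all genes, medians 0.76 and 0.80, camera adjusted p = 3.21e-13 and 5.17e-10). Foxp3, the transcription factor of regulatory T cells, was at 1.49 CPM ± 0.47 against 0.549 ± 0.0764, and Cd3e at 1.2 ± 0.466 against 0.498 ± 0.191. Among 12 dendritic cell and 11 M1-type macrophage genes, 3 each passed when adjusted over the list alone (medians 0.36 and 0.51, camera adjusted p = 0.000118 in both). Itgax stood at 9.15 CPM ± 1.68 against 4.61 ± 1.08, and the interferon-induced chemokines Cxcl10 and Cxcl9 at 14.7 ± 4.4 against 2 ± 1.04 and 29.5 ± 13.2 against 4.38 ± 2.68. Of 6 erythrocyte genes 5 passed when adjusted over the list alone (median 0.82, camera adjusted p = 6.25e-07), led by Alas2.

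Of the other 13 lists called with anti-PD1, 12 were higher and none held with an estimated correlation. The type I interferon response had a median of 0.76 over 18 genes (camera adjusted p = 4.06e-09, adjusted p = 0.26 with an estimated correlation), and its leading member was Bst2. Pan-macrophage genes (median 0.36, 5 of 15 adjusted over the list alone, camera adjusted p = 2.8e-07, 0.13 with an estimated correlation) were led by C1qb, a complement subunit. The CD40 and NF-kappa-B targets (median 0.29, 5 of 15 adjusted over the list alone, camera adjusted p = 7.75e-06, 0.0875 with an estimated correlation) were led by Traf1. Fibroblast genes (median 0.33, camera adjusted p = 2.07e-06), EMT genes (0.25, 0.000834) and hypoxia genes (0.21, 0.00283) each had an adjusted p of 0.26 with an estimated correlation, and Tnc, Mmp13 and P4ha1 led them. Immediate early genes (median 0.16, camera adjusted p = 0.000939, 0.164 with an estimated correlation) were led by Fos and M2-type macrophage genes (0.24, 0.00452, 0.237 with an estimated correlation) by Chil3. Neutrophil genes (median 0.73, 1 of 13 adjusted over the list alone, camera adjusted p = 0.00949, 0.279 with an estimated correlation) were led by Mmp9. Adipose (1.34, 0.0127), pericyte (0.19, 0.0195) and nerve genes (0.22, 0.0284) were led by Cfd, Tagln and S100b, with adjusted p = 0.308, 0.308 and 0.565 under an estimated correlation. Cornification genes were lower, led by Sbsn (median -0.16, camera adjusted p = 0.0164, 0.489 with an estimated correlation). Leaving out anti-PD1 1 ended 7 of these calls (adipose, EMT, fibroblasts, cornification, nerve, neutrophils and pericytes, adjusted p up to 0.815) and anti-PD1 3 that of the M2 list (0.113). Leaving out vehicle 1 ended the adipose call, vehicle 2 the nerve and pericyte calls, and vehicle 4 the neutrophil call (adjusted p up to 0.815).

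The combination was compared with vehicle to find what both drugs together changed. Cytotoxic T and NK cell genes were higher as a group, a list that camera also called higher with every other treatment, and 4 single genes fell. Dusp1 (ENSMUSG00000024190.7, chromosome 17 from 26505590 to 26562128), a phosphatase that inactivates p38 and other MAP kinases, fell from 87.6 CPM ± 8.35 (n = 4) to 51.4 ± 2.73 (n = 5), a log2 change of -0.77 ± 0.11 (adjusted p = 0.0138). Amotl2 (ENSMUSG00000032531.15, chromosome 9 from 102716672 to 102733418), a junction protein that binds the coactivator YAP, fell from 72.5 CPM ± 8.05 to 52.4 ± 2.26 (-0.47 ± 0.07, adjusted p = 0.0138). Mpp2 (ENSMUSG00000017314.12, chromosome 11 from 102057015 to 102088515), a membrane scaffold protein, fell from 20.4 CPM ± 2.28 to 11.1 ± 2.26 (-0.87 ± 0.13, adjusted p = 0.0138). The 4th, A930016O22Rik, lies outside the rule for named genes and was named after its values were seen; it fell from 2.68 CPM ± 0.458 to 1.15 ± 0.231 (adjusted p = 0.0441). No gene rose by this test, while limma with sample weights called 1 higher gene, DESeq2 46 and the fit with the muscle covariate 5, and the smallest p-values among higher genes belonged to Tbl1xr1, Slitrk5 and Pappa, which did not pass (smallest adjusted p = 0.0775). Slitrk5 stood at 1.95 CPM ± 0.656 against 0.377 ± 0.105. An unadjusted p under 0.05 was reached by 1819 genes, against 845 expected, and limma with sample weights called 5 genes and DESeq2 113. The count was 0 without vehicle 1 or combination 2, 2 without vehicle 3, 7 without combination 5, 1 with only the groups compared and 11 with the muscle covariate. Dusp1, Amotl2 and Mpp2 each lost the call without vehicle 1 or combination 2 and 2 of them passed without vehicle 3 (largest adjusted p 0.0681, 0.0681 and 0.108).

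Camera called 13 lists with the combination, 11 higher and 2 lower, and 1 of them, cytotoxic T and NK cells, held with an estimated correlation (adjusted p = 0.0114). Of its 9 tested genes, from 16 listed, 8 passed when adjusted over the list alone and 0 over all genes, with a median log2 change of 1.11 (camera adjusted p = 1.01e-16). The list was not called between the combination and either single drug. Its mean score was -0.73 with vehicle, -0.32 with anti-CD40, 0.04 with regorafenib, 0.09 with anti-PD1 and 0.29 with the combination. Cd8b1 stood at 0.737 CPM ± 0.272 against 0.163 ± 0.0679, Cd3e at 1.23 ± 0.142 against 0.498 ± 0.191, and Cd8a at 1.14 ± 0.587 against 0.3 ± 0.0508 (adjusted p = 0.105, 0.112 and 0.112). The other higher lists had medians between 0.14 and 0.65. T-cell checkpoint genes (median 0.37, camera adjusted p = 0.000121, 0.315 with an estimated correlation) were led by Foxp3. Antigen presentation genes (0.25, 0.000391, 0.617 with an estimated correlation) were led by Nlrc5, and proliferation genes (0.16, 0.000391, 0.545 with an estimated correlation) by Mcm5. Hypoxia genes (0.15, 0.004, 0.54 with an estimated correlation) were led by Slc2a1, at 109 CPM ± 14.8 against 78.1 ± 8.55, and pan-macrophage genes were called too (0.21, 0.0147, 0.589 with an estimated correlation). Fibroblast and EMT genes (0.16 in both, 0.02 in both, 0.682 and 0.589 with an estimated correlation) were also called, and Thy1 led the former. Basal keratinocyte (0.14), lymphatic (0.22) and neutrophil genes (0.65) each had a camera adjusted p of 0.0479 and were led by Itga6, Pdpn and Mmp9 (adjusted p = 0.67, 0.589 and 0.589 with an estimated correlation). In the hypoxia, pan-macrophage and basal lists 1 member each passed when adjusted over the list alone, among them Slc2a1 and Itga6.

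The 2 lower lists of the combination were the immediate early and heat shock genes (median -0.10, camera adjusted p = 0.02, 0.54 with an estimated correlation) and the p38-CREB-KLF4 axis (median -0.02, mean -0.12, camera adjusted p = 0.02, 0.315 with an estimated correlation). Jun led the former, as its 1 member adjusted over the list alone, and Dusp1 the latter, as 1 of 2. Klf4 itself stood at 543 CPM ± 64.8 against 609 ± 49 (adjusted p = 0.643). Single libraries decided 8 of these calls. The basal call was lost without combination 2, 4 or 5 or vehicle 2 or 4 (adjusted p up to 0.287), the EMT call without combination 1 or 4 (0.0653), and the p38 call without combination 4 (0.0653). The fibroblast call was lost without combination 1 or 4 or vehicle 2 or 4 (up to 0.381), the lymphatic call without combination 1, 3 or 4 or vehicle 2 (up to 0.356), and the immediate early call without combination 1 or vehicle 2 (up to 0.192). The pan-macrophage call was lost without combination 1 or vehicle 1 or 4 (up to 0.161), and the neutrophil call without combination 1, 2, 4 or 5 or vehicle 1, 3 or 4 (up to 0.315).

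The anti-CD40 agonist was compared with vehicle in the same model, although the labels' treatment protocol does not name this group, and its schedule is not given in the sources used here. No gene passed, and the lists that camera called rested on few genes and libraries. The smallest p-values belonged to lower genes, and 2 of the first 3 also fell with the combination. Amotl2 stood at 50.5 CPM ± 2.13 (n = 3) against 72.5 ± 8.05 (log2 difference -0.52 ± 0.08, adjusted p = 0.0566) and Dusp1 at 54.5 ± 6 against 87.6 ± 8.35 (adjusted p = 0.185). Gabre lay between them by p (adjusted p = 0.185), and CAAA01147332.1, Ruvbl1 and Tbl1xr1 led the higher ones (adjusted p = 0.521 in each). By edgeR 0 genes passed, 1025 reached an unadjusted p under 0.05 against 845 expected, limma with sample weights called 2 genes and DESeq2 4. Without vehicle 2, or with RLE scaling, or with no filter on low counts, the count was 1. Cytotoxic cell genes (median 0.36, camera adjusted p = 0.0196, 0.943 with an estimated correlation) and proliferation genes (0.12, 0.0332, 0.983 with an estimated correlation) were called higher, each with 1 member adjusted over the list alone, Cd3e and Aurka. Cornification genes (-0.14, 0.0332, 0.983 with an estimated correlation, led by Krt76), mast cell genes (-0.28, 0.0464, 0.943 with an estimated correlation, led by Tpsab1) and the p38-CREB-KLF4 axis (-0.04, 0.0464, 0.793 with an estimated correlation, led by Dusp1) were called lower. All 5 calls were lost without single libraries. These were anti-CD40 3 or vehicle 4 for cytotoxic (up to 0.103) and proliferation genes (up to 0.967), and vehicle 3 or anti-CD40 2 for cornification (up to 0.485). For mast cells they were anti-CD40 1 or 3 or vehicle 3 or 4 (up to 0.293), and for the p38 list anti-CD40 1 or 3 or vehicle 1, 3 or 4 (up to 0.165). The number of lists called was 9 without anti-CD40 2 and 1 without vehicle 4.

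The genes fixed in advance for the comparisons with vehicle comprised 14 checkpoint, macrophage, T-cell and vascular genes, of which 13 were tested and Gzmb, with 86 counts over all libraries, was not. Of these only Cd8a with regorafenib passed (adjusted p = 0.0328), a call lost in 7 of the 8 runs without a library (adjusted p up to 0.104), and 0 passed in the other 3 comparisons. Cd274, which encodes PD-L1, stood at 11.8 CPM ± 5.39 with anti-PD1 against 6.58 ± 1.03 with vehicle (adjusted p = 0.329), and Pdcd1 at 1.17 ± 0.323 with regorafenib against 0.546 ± 0.237 (adjusted p = 0.0706). Cd40 stood at 0.64 ± 0.108 with anti-CD40 against 0.728 ± 0.125 (adjusted p = 0.942). Arg1, Mrc1, Nos2, Csf1r, Kdr and Klf4 did not pass in any of the 4 comparisons.

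**Figure D2:**
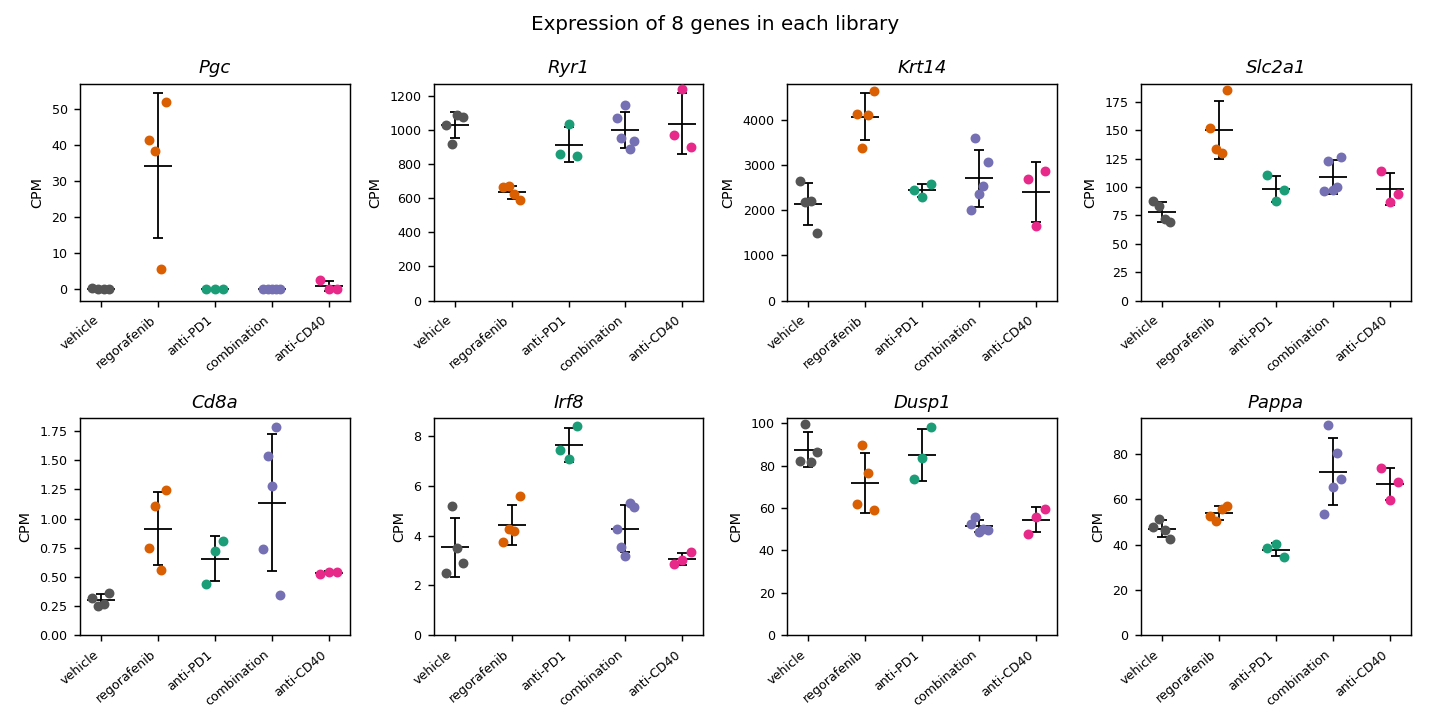
CPM (vertical axes) of 8 genes in each library of the 5 groups (horizontal axes), with points for libraries, horizontal bars for group means and error bars of 1 SD. Pgc is high in the 4 regorafenib libraries, at 5.46 to 51.9 CPM, Ryr1 is lowest there, and Dusp1 is lower in the 5 combination libraries than in the 4 vehicle libraries.

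The combination was compared with regorafenib alone. Skeletal muscle, pericyte, lymphatic and M2-type macrophage genes were higher in the combination, and keratinocyte, proliferation and immediate early genes were lower. None of these list calls held with an estimated correlation (adjusted p = 0.441 to 0.565). Cd163 stood at 18.2 CPM ± 2.55 (n = 5) against 9.18 ± 1.71 (n = 4), a log2 change of 0.99 ± 0.17 (adjusted p = 0.00504). Neb rose from 978 CPM ± 89.3 to 1550 ± 136 (adjusted p = 0.00341) and Abcc9, a potassium channel subunit of pericytes, from 64 ± 7.11 to 103 ± 12.7 (adjusted p = 0.00504). Of 16909 genes, 958 rose and 810 fell, 29 and 19 of them by at least 2-fold, with 4759 at an unadjusted p under 0.05 against 845 expected. The largest falls were the stomach genes, since these were high with regorafenib alone. Pgc was at least 1170-fold lower, Gkn2 at least 295-fold and Atp4b at least 42.6-fold, with 0 counts in the 5 combination libraries, and the count ratio of Clps was 0.00298 (95% interval 0.000613 to 0.00873). Gkn1, Pla2g1b, Mucl3 and Atp4a also fell. The largest rises, between 1.08 and 1.75 on the log2 scale, were Cnksr2, Ackr4, Capn3, Sgcd, Tlr8, Dlk1, Phex and 9930111J21Rik1, and Capn3, a muscle protease, stood at 4.77 CPM ± 0.919 against 2.15 ± 0.219 (adjusted p = 0.00434). Genes that rose had a median exon length of 6467 bases and genes that fell 2594, an order that turned with length and GC offsets (4521 and 5088). With these offsets 1501 genes passed, of which 1094 were among the 1768. The count of 1768 was 716 without combination 1, 800 without combination 3, 942 without regorafenib 1, 1109 without regorafenib 3 and 484 without regorafenib 4. With the muscle covariate it was 5, where the median absolute log2 change of these genes was 0.23 in place of 0.36 with an SE of 0.09 in both fits. Of the 44 named genes that passed, 21 lost the call in no run without a library. Among these 21, Atp4b had a value in only 6 of the 9 runs. Without combination 1 to 5, 25, 38, 30, 39 and 36 passed, and without regorafenib 1 to 4, 31, 29, 28 and 22. Areg lost the call in 7 of the 9 runs, and Birc5, Phex, Plin4 and Sox2 in 6 (adjusted p up to 0.133).

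Between the combination and regorafenib camera called 14 lists, 8 higher and 6 lower, and none held with an estimated correlation. Skeletal muscle genes had a median log2 change of 0.47 (8 of 19 up, 14 adjusted over the list alone, camera adjusted p = 9.14e-08), and the adjusted p was 0.441 with an estimated correlation for this list and for the next 4 higher ones. Of the 16 kinase targets, 6 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.00112), including Ddr2 at 0.54 ± 0.12 and Pdgfra at 0.60 ± 0.13. Of 12 pericyte genes 3 rose (5 adjusted over the list alone, median 0.34, camera adjusted p = 0.00112). Of 8 lymphatic genes 4 rose (4 adjusted over the list alone, median 0.48, camera adjusted p = 0.00426), among them Lyve1, at 19.8 CPM ± 3.57 against 12.3 ± 1.67, and Flt4. Of 15 M2-type macrophage genes, Cd163 and Mrc1 rose (2 adjusted over the list alone, median 0.38, camera adjusted p = 0.00426), where Cd163 passed in all 9 runs without a library and Mrc1 lost the call in 8 (adjusted p up to 0.131). Fibroblast (median 0.32, camera adjusted p = 0.00127, 0.596 with an estimated correlation), type I interferon (0.62, 0.00127, 0.647 with an estimated correlation) and adipose genes (0.77, 0.0204, 0.504 with an estimated correlation) were led by Pdgfra, Rsad2 and Plin4. In these lists 1, 2 and 1 members rose over all genes and 1, 2 and 2 adjusted over the list alone.

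Among lower lists, 3 of 18 proliferation genes fell (3 adjusted over the list alone, median -0.26, camera adjusted p = 5.09e-05, 0.441 with an estimated correlation), led by Birc5, an inhibitor of apoptosis active in mitosis. Of 14 immediate early and heat shock genes 4 fell (8 adjusted over the list alone, median -0.30, camera adjusted p = 7.49e-05, 0.441 with an estimated correlation), led by Ier2. Of 6 erythrocyte genes 1 fell, Hbb-bs (3 adjusted over the list alone, median -0.53, camera adjusted p = 0.0038, 0.441 with an estimated correlation), whose reads can be shared with its near-identical copy. Areg, an epidermal growth factor receptor ligand, was the wound keratin member that fell, from 8.53 CPM ± 3.27 to 4.09 ± 1.01 (1 adjusted over the list alone, list median -0.45, camera adjusted p = 0.00127, 0.504 with an estimated correlation). Of 13 basal keratinocyte genes 3 fell and 1 rose (4 and 1 adjusted over the list alone, median -0.31, camera adjusted p = 0.0038, 0.504 with an estimated correlation), led by Sox2. Sprr1b was the 1 cornification gene that fell (1 adjusted over the list alone, median -0.25, camera adjusted p = 0.00426, 0.565 with an estimated correlation). The basal call was lost without regorafenib 4 (adjusted p = 0.0533) and the adipose call without combination 5 (0.0857). With the muscle covariate 9 of the 14 calls were made, and the basal, cornification, wound keratin, adipose and skeletal muscle calls were not.

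The combination was compared with anti-PD1 alone to find what adding regorafenib changed. Antigen presentation, interferon and immediate early genes were lower as groups in the combination than with anti-PD1 alone, and 1 gene rose. With an estimated correlation these list calls were lost (adjusted p = 0.157, 0.642 and 0.0511 with an estimated correlation), and the interferon call was also lost without anti-PD1 3. Pappa (ENSMUSG00000028370.7, chromosome 4 from 65124174 to 65357509), a protease that cleaves insulin-like growth factor binding proteins, stood at 72.2 CPM ± 14.9 (n = 5) against 37.7 ± 2.95 (n = 3), a log2 change of 0.94 ± 0.13 (adjusted p = 0.0192). Dusp1, Slc25a25 and Amotl2 had the smallest p-values among lower genes and did not pass (adjusted p = 0.0688 in each), with Dusp1 at 51.4 CPM ± 2.73 against 85.2 ± 12.3. An unadjusted p under 0.05 was reached by 1681 genes against 845 expected, limma with sample weights called 10 genes and DESeq2 108. The edgeR count was 0 without anti-PD1 1, anti-PD1 3 or combination 4 and 15 without anti-PD1 2, and Pappa lost its call without the former 3 libraries (adjusted p up to 0.151). With only the groups compared 1 gene was called, lower and not Pappa (adjusted p = 0.267). The edgeR count was 10 with no filter or the salivary gland covariate, 5 with the muscle covariate and 3 with length and GC offsets.

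Camera called 15 lists between the combination and anti-PD1, 14 lower and 1 higher, and none held with an estimated correlation. Of 19 antigen presentation genes 15 passed when adjusted over the list alone (0 over all genes, median -0.57, camera adjusted p = 9.13e-19, 0.157 with an estimated correlation), led by Tapbp and Irf1. Immediate early and heat shock genes had a median of -0.22 (5 of 14 adjusted over the list alone, camera adjusted p = 2.41e-09, 0.0511 with an estimated correlation), led by Jun, at 73.2 CPM ± 5.87 against 99.8 ± 7.58, and Fosb, at 1.36 ± 0.628 against 4.98 ± 2.04. Erythrocyte genes (median -0.66, 4 of 6 adjusted over the list alone, camera adjusted p = 9.22e-06, 0.157 with an estimated correlation) and the CD40 and NF-kappa-B targets (-0.42, 5 of 15 adjusted over the list alone, camera adjusted p = 0.00019, 0.245 with an estimated correlation) were led by Hbb-bs and Nfkbie. T-cell checkpoint genes (-0.39, 0.00107, 0.34 with an estimated correlation) were led by Il2ra. These 5 calls were kept whichever library was left out, while the number of lists called was 9 without combination 4 or 5.

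The other 10 lists called between the combination and anti-PD1 were each lost without at least 1 library. Type I interferon genes (median -0.66, camera adjusted p = 2.6e-05, 0.642 with an estimated correlation, led by Bst2) were lost without anti-PD1 3 (0.0925). Adipose genes (-1.25, 0.0103, 0.393 with an estimated correlation, led by Adipoq) were lost without combination 4 or anti-PD1 1 (up to 0.378), and pan-macrophage genes (-0.13, 0.0163, 0.642 with an estimated correlation, led by Csf1r) without anti-PD1 3 or combination 3 (up to 0.303). Fibroblast genes (-0.18, 0.0266, 0.768 with an estimated correlation, led by Col1a1) were lost without combination 2 or 5 or anti-PD1 1 (up to 0.716), and their direction turned without anti-PD1 1 (0.716). The p38-CREB-KLF4 axis (-0.03, 0.0417, 0.245 with an estimated correlation, led by Dusp1) was lost without anti-PD1 2 or 3 or combination 4 or 5 (up to 0.13). M2-type macrophages (-0.08, 0.0442, 0.484 with an estimated correlation, led by Chil3) were lost without anti-PD1 3 or combination 4 or 5 (up to 0.277). Dendritic cells (-0.20, 0.0463, 0.34 with an estimated correlation, led by Cd83) were lost without anti-PD1 1 or 3 or combination 1, 3 or 5 (up to 0.143), and M1-type macrophages (-0.26, 0.0463, 0.372 with an estimated correlation, led by Irf5) without anti-PD1 3 or combination 3, 4 or 5 (up to 0.295). Endothelial genes (-0.10, 0.0463, 0.768 with an estimated correlation, led by Cldn5) were lost without anti-PD1 1 or combination 2, 4 or 5 (up to 0.389). Proliferation genes were higher (0.07, 0.0463, 0.768 with an estimated correlation, led by Mcm6) and were lost without anti-PD1 2 or combination 3 or 4 (up to 0.701).

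The interaction term tested whether the combination differed from the sum of the changes with regorafenib alone and anti-PD1 alone. Immediate early and erythrocyte genes lay below that sum as lists (adjusted p = 0.0363 in both with an estimated correlation). Antigen presentation, T-cell checkpoint and cytotoxic genes were also called below it and skeletal muscle genes above it, but these calls were lost (adjusted p = 0.251, 0.139, 0.393 and 0.419 with an estimated correlation). Ptgs2 (ENSMUSG00000032487.8, chromosome 1 from 150100031 to 150108227), the inducible cyclooxygenase, had an interaction of -2.74 ± 0.47 on the log2 scale (adjusted p = 0.0192), with 3.96 CPM ± 0.8 in the combination and 3.47 ± 0.935 with vehicle. For Ccl2 it was -2.74 ± 0.55, with 1.34 CPM ± 0.6 in the combination against 4.98 ± 1.23 with anti-PD1 alone. The other 6 of the 8 lowest were Arc, Hbb-bs, Rnd3, H2-DMb1, Pxdc1 and Cxcl14, between -1.45 and -0.94, and the reads of H2-DMb1 can be shared with its paralog. Among the 8 highest, between 1.15 and 2.07, Sgcd was at 1.47 ± 0.22 (adjusted p = 0.0096) and Capn3 at 1.32 ± 0.27, beside Cyp2b19, Cnksr2, Best3, Rian, Ctnna3 and Zfp971. Neb (0.92), Ryr1 (0.82) and Dnajb1 (-0.54) passed as members of called lists. In all 106 genes passed, 76 above the sum and 30 below it, with 2669 at an unadjusted p under 0.05 against 845 expected. Genes above the sum had a median exon length of 13094 bases and genes below it 2986. With length and GC offsets 33 genes passed, 15 above the sum and 18 below it, and 22 of them were among the 106, and the order of the median lengths turned (4375 above and 9036 below). The count was 34, 13 and 15 without vehicle 1, 3 and 4, and 11, 177 and 13 without anti-PD1 1 to 3. It was 37, 53, 38 and 24 without combination 1 to 4, and 33, 56 and 12 without regorafenib 1, 2 and 4. Of the 19 named genes that passed, Sgcd and Rian did so whichever of the 16 libraries was left out, Ptgs2 lost the call without 4 of them, Ccl2 without 10 and Capn3 without 11 (adjusted p up to 0.108). Cyp2b19 lost it without 15, Arc without 14, Hbb-bs, Cxcl14, Dnajb1, Ctnna3 and Cnksr2 without 13 and H2-DMb1 without 12 (adjusted p up to 0.152), and between 3 (without anti-PD1 1 or regorafenib 4) and 16 (without vehicle 2) passed in single runs.

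Camera called 16 lists for the interaction, 14 below the sum and 2 above it. The immediate early and heat shock genes (median -0.47, camera adjusted p = 7.88e-09) and the erythrocyte genes (median -1.37, camera adjusted p = 7.88e-09) held with an estimated correlation (adjusted p = 0.0363 in both). In each, 1 gene passed over all genes and 5 adjusted over the list alone, of 14 and 6. Antigen presentation genes (median -0.56, 12 of 19 adjusted over the list alone, camera adjusted p = 8.97e-12, 0.251 with an estimated correlation) were led by Cd74. T-cell checkpoint genes (-0.86, 5 of 13, 2.05e-06) and CD40 and NF-kappa-B targets (-0.51, 4 of 15, 6.04e-06) were led by Tnfrsf18 and Nfkbie, each with an adjusted p of 0.139 with an estimated correlation. Proliferation (-0.37, 6.04e-06, 0.35 with an estimated correlation), cytotoxic (-0.74, 0.00467, 0.393 with an estimated correlation) and dendritic cell genes (-0.55, 0.00692, 0.154 with an estimated correlation) were led by Aurka, Cd3e and Fscn1. Basal keratinocyte (-0.29, 0.00722, 0.419 with an estimated correlation), hypoxia (-0.21, 0.00767, 0.393 with an estimated correlation) and wound keratin genes (-0.30, 0.0138, 0.477 with an estimated correlation) were led by Pthlh, Slc2a1 and Areg. Neutrophil (-0.53, 0.0244, 0.419 with an estimated correlation), EMT (-0.33, 0.0424, 0.501 with an estimated correlation) and unfolded protein response genes (-0.18, 0.0496, 0.477 with an estimated correlation) were led by Ngp, Snai2 and Phgdh. Skeletal muscle genes lay above the sum, with 2 of 19 over all genes and 3 adjusted over the list alone (median 0.39, camera adjusted p = 9.47e-06, 0.419 with an estimated correlation), as did the kinase targets, led by Ddr2 (0.27, 0.0236, 0.393 with an estimated correlation). With the muscle covariate 10 of the 16 calls were made, and the basal, wound keratin, EMT, unfolded protein, kinase target and skeletal muscle calls were not. Calls were lost without anti-PD1 3 for cytotoxic genes (adjusted p = 0.0579), without vehicle 4 for wound keratins (0.0661), and without vehicle 4 or anti-PD1 3 for kinase targets (up to 0.0643). The neutrophil call was lost without combination 3, vehicle 4 or anti-PD1 1 (up to 0.209). The EMT call was lost without vehicle 1, regorafenib 1 or 4, anti-PD1 1 or combination 2, 3 or 5 (up to 0.429), and the unfolded protein call without vehicle 3 or 4, regorafenib 2 or 3, anti-PD1 1 or 2, or combination 1, 3 or 4 (up to 0.165).

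**Figure D3:**
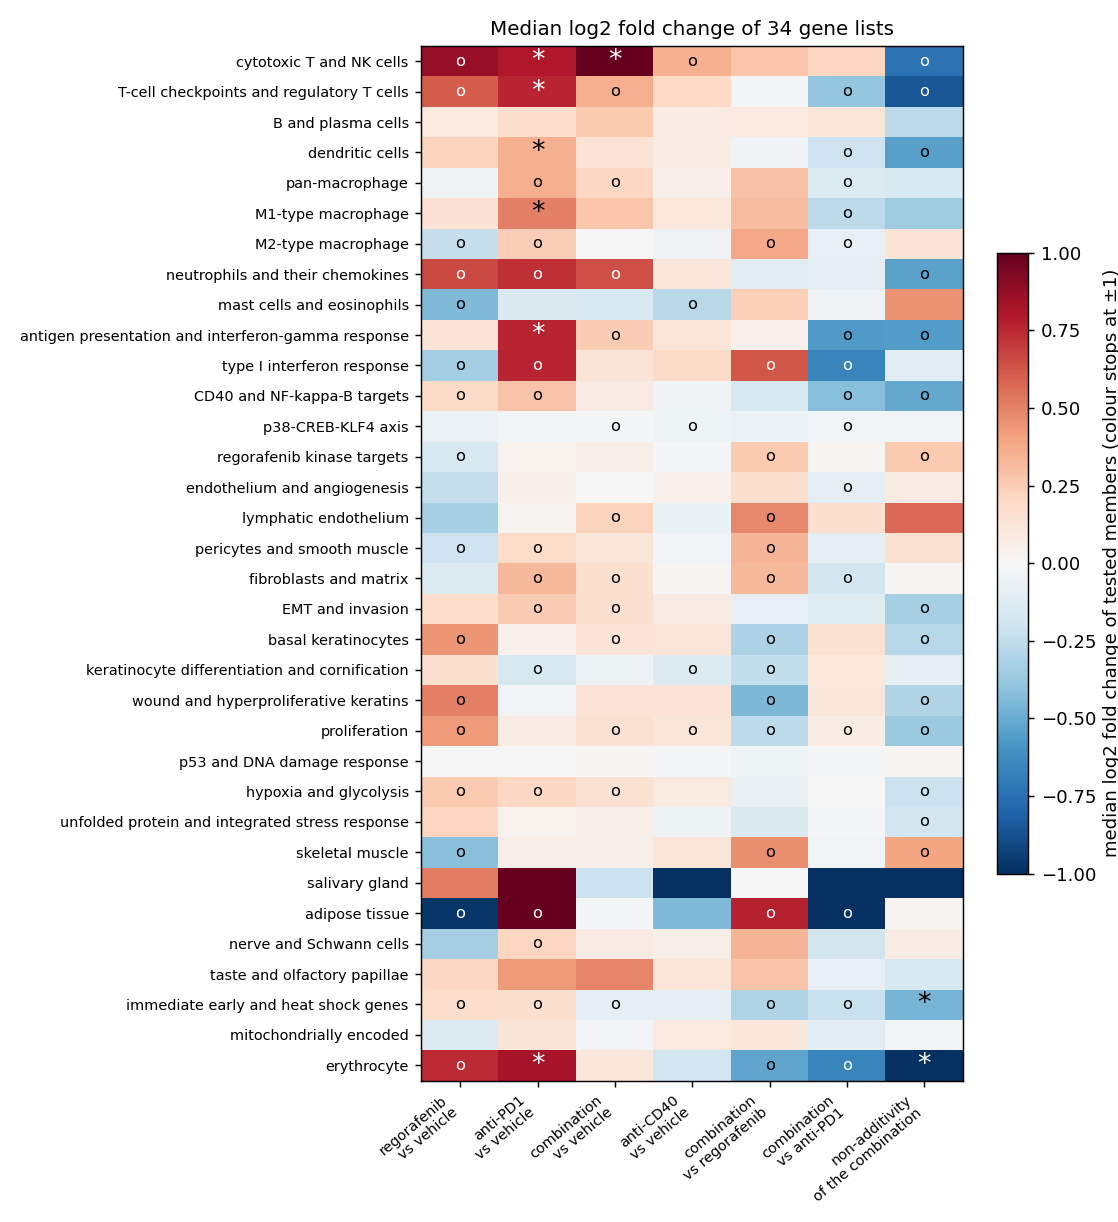
Median log2 fold change of the tested members of 34 gene lists (rows) in the 7 comparisons (columns), in colour from -1 (blue) to 1 (red), where the colour stops. A circle marks a list that camera called with its preset correlation and an asterisk one that also held with an estimated correlation, which 9 cells show: 6 with anti-PD1, 1 with the combination and 2 for the interaction.

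The treatments were compared through their fold changes against the shared vehicle libraries. Amotl2 and A930016O22Rik fell with both regorafenib and the combination, and these 2 shared falls stand beside 0.12 for independent lists of the same sizes, a value that leaves out the shared vehicle libraries. Across 16909 genes, which are not independent replicates, the correlation of fold changes was 0.408 for regorafenib and the combination, beside 0.524 for simulated unchanged groups against the same controls. The covariance was 0.0468 beside 0.0488 simulated, and with the vehicle libraries split 2 and 2 it averaged -0.00655 over 3 splits (-0.031 to 0.00588). For anti-PD1 and the combination the correlation was 0.559 (0.476 simulated) and the covariance 0.056 (0.0473 simulated, 0.0145 with split vehicle libraries, -0.00291 to 0.0246). Covariances of the other 4 pairs were 0.0574 for regorafenib and anti-PD1, 0.0574 for regorafenib and anti-CD40, 0.0214 for anti-PD1 and anti-CD40 and 0.0333 for the combination and anti-CD40, against 0.05, 0.0492, 0.0488 and 0.047 simulated. Genes that rose with regorafenib, by a median log2 change of 0.37, had medians of 0.13 in the combination, 0.13 with anti-CD40, which contains no regorafenib, and 0.07 with anti-PD1. The sign was the same for 486, 518 and 415 of the 562 (86.5%, 92.2% and 73.8%). In 20 simulations in which only the regorafenib group changed, the shared vehicle libraries gave 64.6%, 61.7% and 61.2%. These simulations called 204 to 264 of the rises. They drew each gene independently, as did those of unchanged groups, so they hold no differences in tissue content that move many genes together. With regorafenib called against 2 vehicle libraries and the others set against the remaining 2, chosen after the data were seen, the shares averaged 79.8%, 80% and 59.6% over 6 splits with 8 to 511 rises. Genes that fell with regorafenib, by a median of -0.47, had medians of -0.02, -0.03 and -0.05, and the sign was the same for 291, 294 and 330 of 507 (57.4%, 58% and 65.1%). The simulations gave 63.9%, 62.6% and 62.6% and the splits 39%, 44% and 52%.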

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

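The tests of stomach genes, of Dusp1 and of the regorafenib rises and falls in the combination were chosen after the results were seen, as were the salivary gland covariate and the length and GC offsets. The other tests in this part were set beforehand, except that a criterion on the size of the fold changes was added to the muscle test after its count was known.

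The first pattern is the 1069 genes called with regorafenib alone. With length and GC offsets 1022 genes passed, of which 811 were among the 1069. With the salivary gland covariate 1580 passed, of which 1068 were among the 1069. These counts argue against length and GC bias or gland content as the whole cause. Stomach list genes made up 10 of the 562 rises, but a list of 22 genes could not reach the share of the rises set as the mark of stomach RNA. That test therefore decides nothing about stomach RNA. With the muscle covariate 86 passed, below the fifth that was set beforehand as the mark of muscle content as the cause, but the median absolute log2 change fell only from 0.42 to 0.32 with an SE of 0.10 in both fits and lists unrelated to muscle moved in opposite directions, so muscle content and regorafenib cannot be told apart here. An effect shared with the combination is argued against for the falls, whose median in the combination was 0.0441 times that with regorafenib, while for the rises the ratio of 0.339 (0.255 with split vehicle libraries, 0.0822 to 0.444) decides neither way, beside 0.357 with anti-CD40, which contains no regorafenib, and 0.0791 in simulated unchanged groups. Over all genes, 1 of the 3 splits of the vehicle libraries gave a covariance at or below 0 (-0.031). That was set beforehand as evidence against such an effect. The other splits gave 0.00543 and 0.00588 (mean of all 3 -0.00655). Without splits the covariance was 0.0468, beside 0.0488 in simulated unchanged groups. By the rule set beforehand these values argue against a shared effect over all genes, but splits of both signs do not exclude one.

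The second pattern is the stomach genes in the regorafenib libraries, where Pgc had 2848 counts over the 4 libraries, Gkn1 898 and Atp4b 104. Of 22 listed genes, 8 of which prompted the list, 18 had higher CPM there than in the vehicle and combination libraries, by a test of summed counts that covers counting error only, with genes of 4 of 4 cell classes (pit, chief, parietal and endocrine). Among the other 14 genes 10 were higher, again from 4 of 4 classes, which is consistent with stomach tissue or its RNA in these libraries as a candidate source. Gland content of the tongue is argued against: over 19 libraries the stomach and salivary gland scores had a Spearman rho of 0.293 (permutation p = 0.224) and a Pearson r of -0.0548 (permutation p = 0.824; -0.0631 without the 2 farthest libraries), and vehicle 2, combination 5 and anti-PD1 2, with the highest gland scores, held 5.23, 6.47 and 5.42 CPM of the 22 genes against 146 in regorafenib 4, whose gland score was -1.04. Induction by regorafenib regardless of anti-PD1 is argued against, since the excess of the 22 genes over vehicle in the combination libraries averaged 0.00906 of that with regorafenib alone (-0.00927 to 0.0385), while induction that anti-PD1 prevents, and how stomach RNA could have entered the samples, stay open and untested. The 22 genes held 18.5 CPM in anti-CD40 1, without regorafenib, and 14.2 in regorafenib 3, so such a level was not confined to the regorafenib group. In anti-CD40 2 and anti-CD40 3 they held 2.89 and 2.24 CPM.

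The third pattern is lower Dusp1 with the combination. High vehicle libraries are argued against as the whole cause, since the log2 difference from the anti-PD1 libraries was -0.73 (-0.729). Dusp1 also stood at 54.5 CPM ± 6 (n = 3) with anti-CD40, beside 51.4 ± 2.73 (n = 5) with the combination, so a low level was not particular to the combination. A lower immediate early response in the samples may contribute: camera gave that list an adjusted p of 0.02, but 0.54 with an estimated correlation, and 5 of its 14 genes were higher, so this and an effect of the combination cannot be told apart.

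Whether chance could give as many calls was tested by regrouping the same libraries. For genes, 1 of 35 splits (the real one) gave 1069 or more calls for regorafenib (highest other 0). For the combination, 1 of 100 gave 4 against vehicle (highest other 2) and 1 of 100 gave 1768 against regorafenib (highest other 621). This argues against chance for these counts without excluding it, since 1 of 35 is the smallest share possible for regorafenib. For the interaction 1 of 100 gave 106 (highest other 4). There the labels of all 4 groups were shuffled, which tests for any difference between the groups, so it does not decide about the interaction. For the combination against anti-PD1, 2 of 56 splits gave 1 call or more, and the other one gave 70. This may reflect a structure of the samples, which was not identified or tested. For anti-PD1 and anti-CD40 the real count was 0, which all 35 of 35 splits reach by construction, so nothing was tested there (highest other 1 and 10). For lists, as many calls came from 4 of 35 splits with regorafenib (17 lists, highest other 23), 3 of 35 with anti-PD1 (19, 21), 16 of 100 with the combination (13, 17) and 34 of 35 with anti-CD40 (5, 21). It was 23 of 100 for the combination against regorafenib (14, 19), 4 of 56 against anti-PD1 (15, 16) and 16 of 100 for the interaction (16, 20), so chance cannot be excluded for the number of lists in any comparison.

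The change with regorafenib differed with and without anti-PD1, by the test of the interaction, for 106 genes and 16 lists, of which 2 lists held with an estimated correlation. With length and GC offsets 33 genes passed, 22 of them among the 106, and with the muscle covariate 39, 32 of them among the 106. Genes above the sum had a median exon length of 13094 bases, against 3942 for all tested genes. Transcript length and muscle content were therefore not separated from an interaction of the drugs. The 19 genes named for this test are given here with Ankrd12 and Mycbp2, which were named for anti-PD1 against vehicle. Cyp2b19 (2.07), Cnksr2 (1.97), Sgcd (1.47), Capn3 (1.325), Best3 (1.25), Rian (1.24), Ctnna3 (1.19), Zfp971 (1.15), Neb (0.92), Ryr1 (0.82), Ankrd12 (0.51) and Mycbp2 (0.49) lay above the sum of the single drugs on the log2 scale. Below it were Dnajb1 (-0.54), Cxcl14 (-0.94), Pxdc1 (-0.97), H2-DMb1 (-1.02), Rnd3 (-1.08), Hbb-bs (-1.39), Arc (-1.45), Ccl2 (-2.74) and Ptgs2 (-2.74).

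In 29 of 523 groups of 4 or 5 libraries 1 library lay far from the others, about the 1 in 20 that chance gives, by the gap to its nearest neighbour as a share of the range. In vehicle 2 the adipose score (0.878), Adipoq (0.87), Nfkbie (0.839) and Bpifb2 (0.905) were high. Gkn1 in vehicle 3 and Gkn2 and Mucl3 in vehicle 4 were high (share 1, from 1 or 2 counts), and CAAA01147332.1 in vehicle 3 (0.835) and Rian in vehicle 1 (0.907) were low. In regorafenib 3, Pgc (0.864) and Clps (0.915) were low, and Cfd (0.885), Sbsn (0.85) and the unfolded protein score (0.849) were high. In regorafenib 4 the M2-type macrophage score was high (0.83) and the cornification score low (0.884). Chil3 (0.956) was high and the lymphatic score (0.854) low in regorafenib 2, and Ruvbl1 (0.88) was high and Sox2 (0.872) low in regorafenib 1. Among the combination libraries, the erythrocyte score (0.843) and Hbb-bs (0.827) were high and Nlrc5 (0.714) and Pdcd1 (0.78) low in number 3, and Lyve1 (0.751) was high in number 1. Tpsab1 (0.789) and Mucl3 (share 1) were high in number 4, Cnksr2 (0.896) was low in number 5 and Il2ra (0.772) low in number 2.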

How the results depend on the processing

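The salivary gland covariate, the length and GC offsets, the block by column number and the split of the vehicle libraries for the regorafenib calls were chosen after the data were seen, and the other alternatives before. Of the 111 passing results of named genes, none reversed under any alternative, and 109 passed with RLE scaling, 85 with no filter, 109 with the gland covariate, 86 with offsets, 105 with limma, 99 with DESeq2 and 22 with the muscle covariate. Left-out libraries gave 50 (without regorafenib 4) to 107, with 71 without vehicle 4. The cause of the changes below was not tested unless stated. Requiring an absolute log2 change of 1 left 80 genes for regorafenib, 1 for the combination, 48 for the combination against regorafenib, 0 against anti-PD1 (by edgeR, with 1681 at an unadjusted p under 0.05, and 108 by DESeq2 without the fold threshold) and 22 for the interaction. RLE scaling gave 1 for anti-CD40. No filter gave 3 for anti-PD1, 1 for anti-CD40, 1094 for the combination against regorafenib and 10 against anti-PD1. The muscle covariate gave 86, 2 and 11 for regorafenib, anti-PD1 and the combination, 5 each for the combination against regorafenib and anti-PD1, and 39 for the interaction. The gland covariate gave 10 for the combination against anti-PD1 and 263 for the interaction, and the offsets 3 and 33. Only the groups compared gave 1 for the combination and 164 for the interaction. Limma with sample weights gave 1673 for regorafenib, 3 for anti-PD1, 2 for anti-CD40, 3052 for the combination against regorafenib, 10 against anti-PD1 and 200 for the interaction. DESeq2 gave 1651, 71, 113 and 4 against vehicle, 108 for the combination against anti-PD1 and 566 for the interaction.

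The replicate numbers of the titles were not taken as a pairing: the deviations of same-numbered libraries had a mean correlation of 0.0902 over 33 pairs, with 17 above 0.1 and the lowest -0.556, against -0.0279 over 110 other pairs, with 46 above 0.1. The numbers of the deposited columns differ from the titles in 4 vehicle and regorafenib libraries. By those numbers the means were 0.0649 over 27 pairs (13 above 0.1) and -0.0159 over 116 (50 above 0.1). The replicate block gave 5 genes for the combination, 3 higher and 2 lower, with 2 of the 4 falls among them, 0 genes for the combination against anti-PD1, 36 for the interaction and 9 lists for the combination against anti-PD1. The replicate block by column number, in which vehicle 4 has a number of its own and so no weight in the comparisons, gave 35 genes for regorafenib, 1 for the combination, 0 for the combination against anti-PD1 and 3 for the interaction, 2 lists for anti-CD40, and 47 passing results of named genes.

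With an estimated correlation, camera called 0, 6, 1 and 0 lists for regorafenib, anti-PD1, the combination and anti-CD40, 0 for the combination against each single drug and 2 for the interaction, and fry called 7, 7, 2, 0, 8, 1 and 5 in the same order. No filter gave 3 lists for anti-CD40, the muscle covariate 11 for regorafenib, and the offsets 3 for anti-CD40 and 9 for the combination against anti-PD1. Without single libraries, genes called ranged from 269 to 1139 for regorafenib, 0 to 2 for anti-PD1, 0 to 7 for the combination, 0 to 1 for anti-CD40, 484 to 1747 for the combination against regorafenib, 0 to 15 against anti-PD1 and 11 to 177 for the interaction. Lists called ranged from 14 to 21, 12 to 22, 7 to 15, 1 to 9, 14 to 17, 9 to 16 and 12 to 19 in the same order, with 12 for anti-PD1 without anti-PD1 1 and 7 for the combination without combination 1 or 4. With the vehicle libraries split 2 and 2, which removes the shared controls, mean covariances were 0.00895 for regorafenib and anti-PD1, -0.00655 for regorafenib and the combination, -0.0263 for regorafenib and anti-CD40, 0.0145 for anti-PD1 and the combination, -0.0504 for anti-PD1 and anti-CD40 and -0.043 for the combination and anti-CD40. For the genes that fell with regorafenib the same splits turned the ratio of the median in the combination to that with regorafenib from 0.0441 to -0.0568. The first component held 43.8% of the variance of the 2000 most variable genes. The filter removed Atp4b in 3 of the 8 runs without a library of the regorafenib comparison. The combination against regorafenib has a value for it in 6 of 9. Depth limits genes such as Gzmb, with 86 counts in all libraries.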

Other observations

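The comparison of signs and the look at stomach genes beside Xist were chosen after results were seen, and the other tests in this part before. Lists of salivary gland, p53 response, B and plasma cell, taste papilla and mitochondrial genes were called in no comparison. Salivary gland genes, the transcripts that vary most between libraries, had medians from -2.47 with anti-CD40 to 1.47 with anti-PD1 and 0 of 11 genes passed (camera adjusted p 0.0728 to 0.976 over the 7 tests). The 14 genes of the p53 and DNA damage response, tested because 4NQO damages DNA, had camera adjusted p from 0.595 to 0.981. Of these 1 rose in the combination against regorafenib (2 up and 2 down adjusted over the list alone). B and plasma cell genes (5 tested, camera adjusted p 0.203 to 0.966) and taste papilla genes (7 tested, 0.0853 to 0.966) held no passing gene over all genes and 1 each with anti-PD1 adjusted over the list alone. The 13 mitochondrially encoded genes held none (0.07 to 0.899). The 18 endothelial genes, a tissue that regorafenib targets, were called lower in the combination against anti-PD1 (camera adjusted p = 0.0463, 0.768 with an estimated correlation). With regorafenib alone their median was -0.24 (camera adjusted p = 0.0569), with 0 passing over all genes and 3 lower adjusted over the list alone.

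The median, the mean and the test of a list agreed in sign in all 99 list results that camera called, and differed in 30 of the 139 that it did not call. Among these was the salivary gland list with regorafenib, with a median of 0.51 and a mean of -0.82.

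The sex genes were read as a check of the labels. The 4 Y-linked genes were high in all 19 libraries. Xist, which is expressed from the inactive X chromosome of females, had 150 counts in anti-CD40 1 and 0 to 17 in each other library. The library anti-CD40 1 also held 355 counts of the 22 stomach genes, the most outside the regorafenib group.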
